A study of Mus musculus with 4 samples.

How the data were processed

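Single-cell RNA sequencing was performed on CD4 T cells sorted from the lungs of female mice aged 8 to 16 weeks. Per the labels' protocols, T cells carrying a transgenic receptor for ovalbumin (the DO11.10 or OT-II line) were cultured toward the Th2 state for 6 days, 20000000 of them were injected into each recipient of matching background, and 100 µg of ovalbumin was then given through the nose. A phycoerythrin-coupled antibody against CD45 was injected into the bloodstream 3 minutes before the animals were killed, so that cells inside vessels were stained and cells in the tissue were not. Lungs were digested with collagenase for 30 minutes, and droplet libraries were made with the Chromium 3′ chemistry. Groups were taken from the sample titles: 2 libraries are labelled TRM (tissue-resident memory, antibody-negative) and 2 are labelled circulating (antibody-positive). The labels do not say that the 2 replicates of a group came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

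The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, in filtered feature-barcode matrices. Per the submitters' processing notes, Cell Ranger, Seurat and the mm10 mouse genome were used; their versions and the role of Seurat are not given in the sources used here. Each matrix lists the same 32285 features, and 32158 of their Ensembl identifiers were matched to the GENCODE M21 annotation of the same assembly, from which coordinates were taken.

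The matrices hold 36757 barcodes in all. Totals per library and the precision they give are stated with the results. Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Across the libraries, 860 barcodes failed the gene or UMI minimum and 1168 exceeded the mitochondrial limit. Scrublet, run per library with an expected rate of 8%, marked 5 cells over the 4 libraries, which is too few for the caller to have worked, so doublets were in effect not removed. The 35407 remaining cells were normalized to 10000 counts, log-transformed and clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1 with seed 0. T cell receptor, immunoglobulin, mitochondrial and ribosomal genes were left out of the clustering, and libraries were not integrated.

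The clustering gave 15 clusters. A cluster was set apart as non-T when at least 3 of its 10 leading genes were markers of another cell type, called Treg-like when at least 3 Treg markers including Foxp3 were at least 2-fold higher than in the other cells, and called naive-like when at least 4 of 7 naive markers were. The marker lists were fixed before the data were examined, as were the groups, the cell filters, the tests, most of the alternatives, the 19 gene lists and the rule for named genes. The minimum numbers of markers were set after the clusters had been seen. Trac was detected in 93.6% to 99.9% of the cells of every cluster except cluster 8, where it was in 60.6%, although Cd3e was detected in 68.9% of cluster 14. Cd4 was detected in 14.4% to 39.1% of the cells of clusters 4, 9, 10, 13 and 14, found mostly in the libraries labelled circulating, and in 41.8% to 83.1% of the other T-like clusters, found mostly in those labelled TRM. The population called T-like is therefore every sorted cell outside that cluster, 35270 cells, and the 137 cells of cluster 8 are called non-T. The conventional class is the T-like population without the Treg-like cluster 5 and the naive-like cluster 11.

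Counts were summed per library over each class, and the sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit and F test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Positive log2 fold changes are higher in the libraries labelled TRM. CPM values are counts of the summed class scaled to its total, given as mean ± SD over 2 libraries. A class was tested only if every library held at least 50 of its cells. The Treg-like class had 18 and 7 cells in the libraries labelled circulating and the naive-like class had 7 in each, so the tests within these classes and the test of the difference between Treg-like and conventional cells were not run. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the 19 lists. The lists cover residency, egress and lymph node homing, naive and stem-like cells, Th2, Th1 and cytotoxic, Th17, Treg, Tfh, TCR and NF-kB response, dissociation and immediate early genes, proliferation, interferon response, glycolysis and hypoxia, lipid handling, chemokine receptors, integrins and adhesion, chromatin regulators, inhibitory and costimulatory receptors, and cytokine receptors.

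Shares of cells with a UMI were computed after each cell was thinned to 2000 UMIs, and shallower cells were left out. Intervals are exact binomial 95% intervals and cover counting error only. Group differences in shares were tested with an exact permutation test of the library values, two-sided, in which 2 libraries against 2 cannot give a p below 0.33. Genes named in the text are a panel of 24, the 10 highest and 10 lowest log2 fold changes of each comparison and up to 4 members per gene list. The highest and lowest were taken among genes past the threshold with a mean of at least 20 CPM and no overlap between groups, without receptor segments, mitochondrial, ribosomal and haemoglobin genes, unnamed gene models and markers of other cell types. Some genes chosen by these rules are not reported here. The few other genes named were chosen after their values were seen.

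The procedure was tested on simulated counts with 200 changed genes. For all T-like cells (12900 genes) it recovered 71.6% of 1.5-fold, 92.3% of 2-fold and 97.0% of 4-fold changes, and 2.27% of its calls were unchanged genes. For conventional cells (12714 genes) the shares were 84.8%, 85.1% and 97.0%, with 4.32% of calls unchanged. In each simulation a list of 20 genes raised 2-fold was called by camera, and 0 of the lists of unchanged genes were, among 100 lists in all. The simulated genes varied independently of each other, so false calls of lists with correlated members could not appear. Only 200 genes were changed, so these error rates need not hold where most genes differ, as in the data.

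Alternatives were RLE scaling, library totals only, DESeq2 1.42.0, no filter on low counts, a replicate block, each library left out, called doublets kept (with the cells clustered anew), at most 5% mitochondrial UMIs, and cells thinned to 2000 UMIs. All cells, genes without ribosomal and mitochondrial ones, and equal numbers of cells were tried for the T-like population, and resolutions 0.5 and 2 and clusters made without called genes for the conventional class. Shares were also computed unthinned and at 1000 UMIs. A fold threshold of 2, removal of the 8% of cells with the highest doublet scores, removal of the cluster with 3 naive markers, and leaving libraries out of the list tests and shares were chosen after seeing the data.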

Results

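The data are transcript counts of single lung CD4 T cells, sorted into an antibody-negative fraction labelled TRM and an antibody-positive fraction labelled circulating, with 2 libraries of each. The libraries labelled TRM held 52926547 and 54151017 UMIs over 10525 and 9187 barcodes, and those labelled circulating 37615749 and 37307337 UMIs over 9151 and 7894 barcodes. Kept cells had median depths of 4444.5 and 5185 UMIs in the libraries labelled TRM and 3711 and 4264 in those labelled circulating. Median mitochondrial shares were 3.59% and 3.49% against 3.04% and 3.01%. The study set out to find which transcripts go with tissue residency and which with circulation in CD4 T cells of the lung.

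Over all T-like cells, S1pr1, Klf2 and Ccr7 were higher in the libraries labelled TRM, and Cd69, Cxcr6 and Il1rl1 were higher in those labelled circulating. S1pr1, the receptor that draws T cells out of tissue along a sphingosine-1-phosphate gradient, was at 178 ± 0.760 against 16.5 ± 0.531 CPM (labelled TRM against labelled circulating, mean ± SD, n = 2), 10.4-fold higher. Klf2, a transcription factor that activates S1pr1, was at 942 ± 28.7 against 203 ± 18.3 CPM. Cd69, whose protein removes S1PR1 from the cell surface, was at 358 ± 3.62 against 827 ± 49.2 CPM, and Cxcr6, a chemokine receptor of lung-resident T cells, at 187 ± 9.12 against 409 ± 24.0 CPM. These directions of S1pr1, Klf2, Cd69 and Cxcr6 run opposite to what the group names would lead a reader to look for, so the groups are called by their labels throughout and each direction below refers to the label only.

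Of 13126 genes tested with edgeR, 4160 were higher and 4270 lower in the libraries labelled TRM, of which 1022 and 1210 differed at least 2-fold. The replicates of a group were very close, with a biological coefficient of variation of 4.87%, so that small differences passed the threshold. DESeq2 called 3500 higher and 2580 lower, and a test against a 2-fold change, chosen after the data had been seen, called 615 and 497. RLE scaling gave 4322 higher and 4092 lower, and library totals only gave 4621 and 3755, so which direction held more genes depended on the scaling.

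Of the panel genes, Ccr7, the receptor for lymph node chemokines, had a log2 fold change of 2.63 (SE 0.09). Itgae, encoding the integrin CD103, rose with a log2 fold change of 3.91 (SE 0.10) and Foxp3, the regulatory T cell factor, with 4.30 (SE 0.12). The Th1 genes Ifng and Tbx21 were at 1.08 (SE 0.09) and 0.50 (SE 0.11), Il17a at 1.66 (SE 0.37) and Prdm1 at 0.26 (SE 0.10). Il1rl1, encoding the receptor for interleukin 33, was at -1.30 (SE 0.05), and the Th2 cytokine genes Il5, Il13 and Il4 at -1.68 (SE 0.09), -0.71 (SE 0.07) and -0.40 (SE 0.07). Rgs1 was at -0.65 (SE 0.06), Cd44 at -0.59 (SE 0.06), Bhlhe40 at -0.44 (SE 0.06), Areg at -0.41 (SE 0.06) and Gata3, the Th2 master regulator, at -0.21 (SE 0.06). All of these passed the threshold of edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, the weakest being Prdm1 with an adjusted p of 0.0298. Itga1 did not pass (log2 fold change -0.28 (SE 0.18), edgeR, Benjamini-Hochberg adjusted p = 0.179), except without circulating replicate 2, where it was at -0.49. Zfp683 was too rare to be tested, with 3 and 2 UMIs in the libraries labelled TRM and 9 and 6 in those labelled circulating.

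Several of these panel calls were narrow. With cells thinned to 2000 UMIs, Prdm1, Gata3, Il4, Areg and Tbx21 no longer passed, at log2 fold changes of 0.20, -0.14, -0.06, -0.10 and 0.30. Prdm1 was also lost without circulating replicate 1 (0.18), without TRM replicate 2 (0.15), with DESeq2 and with the highest doublet scores left out, Gata3 without TRM replicate 1 (-0.20), without TRM replicate 2 (-0.20) and with library totals only, and Il17a with equal numbers of cells (1.31). Il17a was at 1.05 without circulating replicate 1 and 2.72 without circulating replicate 2, passing in both.

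**Figure D1:**
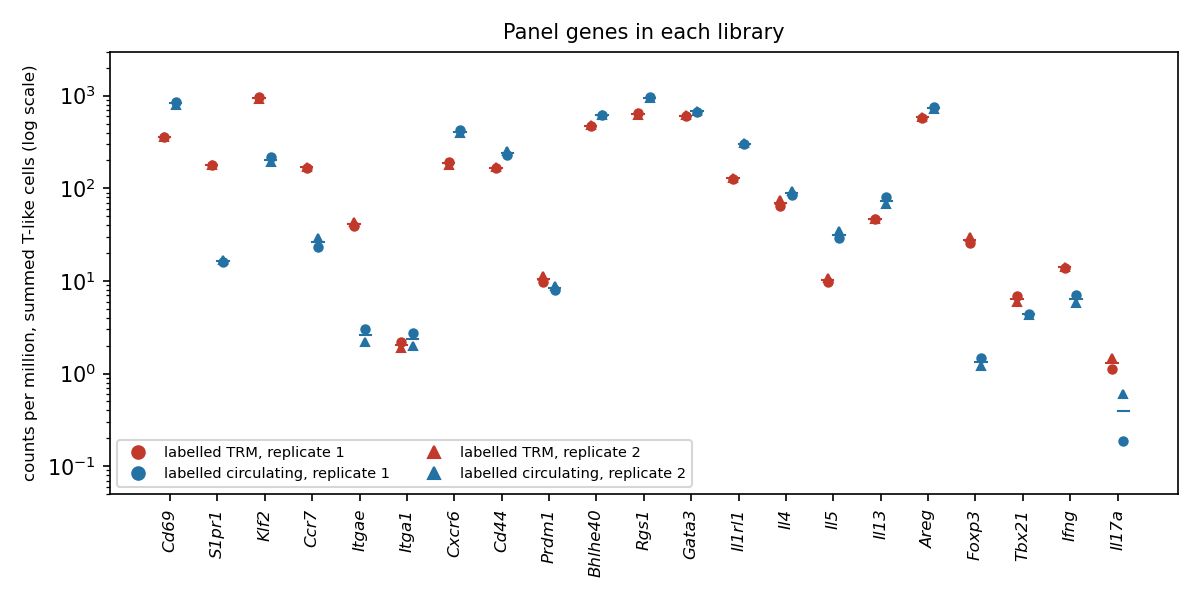
CPM of panel genes (log axis) in each library, over the summed T-like cells, with points for libraries and lines for group means. S1pr1 lies at 178 CPM in the libraries labelled TRM and 16.5 CPM in those labelled circulating, and Cd69 at 358 and 827 CPM.

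The 10 highest genes by the naming rule were Ikzf2, Gzmb, Cd7, Itgae, Pglyrp1, Ms4a4b, Ly6a, Rhoc, S1pr1 and Cdc25b. Of these, Ikzf2, Gzmb, Itgae and Ly6a are leading genes of the Treg-like cluster 5, as are Klrg1 and Ccr3, named below. That cluster held 876 and 817 cells labelled TRM and 18 and 7 labelled circulating. Ikzf2, encoding the Treg-associated factor Helios, was at 50.1 ± 0.337 against 1.76 ± 0.831 CPM, 27.4-fold higher, and Cd7, a T cell surface receptor, at 46.0 ± 0.101 against 2.37 ± 0.380 CPM, 18.6-fold higher. Ms4a4b, a membrane protein of T cells, was at 862 ± 38.7 against 60.1 ± 0.0924 CPM. Gzmb, encoding granzyme B, was 18.8-fold higher (edgeR, Benjamini-Hochberg adjusted p = 0.00501), and its adjusted p was 0.0795 without TRM replicate 1 and 0.0794 without TRM replicate 2. With the replicate block Gzmb did not pass. The 10 lowest were Hlf, Pde3b, Sdc4, Fgl2, Ctla2a, St6galnac3, Gpr65, Ccr8, Ier5l and Spata7. Hlf, a PAR-family transcription factor, was at 5.05 ± 0.530 against 63.8 ± 2.09 CPM, 13.1-fold lower, and Pde3b, a cyclic nucleotide phosphodiesterase, at 4.95 ± 0.0857 against 42.9 ± 0.807 CPM, 9.01-fold lower. Fgl2, a fibrinogen-like protein, was at 35.9 ± 0.931 against 256 ± 14.5 CPM, and Gpr65, a proton-sensing receptor, at 35.9 ± 0.731 against 183 ± 23.6 CPM. Ccr8, a chemokine receptor of Th2 cells, was at 11.4 ± 1.58 against 56.0 ± 10.4 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.00754), and its adjusted p was 0.0547 without TRM replicate 2.

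On the mm10 assembly the annotation places S1pr1 (ENSMUSG00000045092) on chromosome 3 from 115710433 to 115715072, Klf2 (ENSMUSG00000055148) on chromosome 8 from 72319033 to 72321656 and Cd69 (ENSMUSG00000030156) on chromosome 6 from 129267325 to 129275436. It places Cxcr6 (ENSMUSG00000048521) on chromosome 9 from 123806475 to 123811760, Foxp3 (ENSMUSG00000039521) on chromosome X from 7573644 to 7595245 and Hlf (ENSMUSG00000003949) on chromosome 11 from 90336536 to 90390895. All are protein-coding genes, and the counts are for whole genes.

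**Figure D2:**
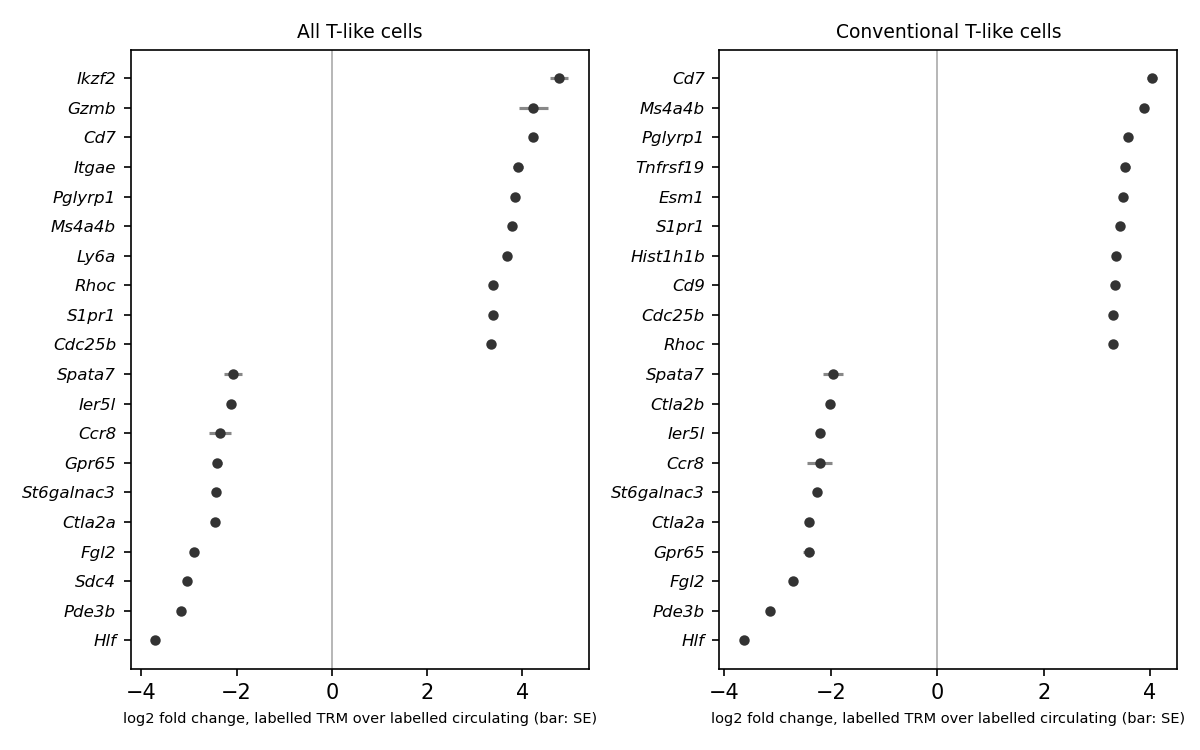
Log2 fold changes (labelled TRM over labelled circulating) of the 10 highest and 10 lowest genes by the naming rule, in all T-like cells (left) and in conventional cells (right), with bars for standard errors. Ikzf2 lies at 4.77 and Hlf at -3.71 on the left, and Cd7 at 4.03 and Hlf at -3.63 on the right.

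Of the gene lists, 13 of 19 were called by camera at the preset correlation, 11 higher and 2 lower in the libraries labelled TRM. With an estimated correlation camera called 0 of the 19, of which 3 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 19. Camera with an estimated correlation rests on the 2 residual degrees of freedom of these libraries. The proliferation list had an estimated correlation of 0.0111, near the preset 0.01, yet its unadjusted camera p went from 2.0e-09 to 0.0270. Those 0 calls therefore cannot tell whether correlated members made the calls at the preset value.

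The egress and lymph node homing list rose, with 12 of its 16 measured members higher and 3 lower, and 12 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 8.6e-04; adjusted p = 0.213 with an estimated correlation). Besides S1pr1, Klf2 and Ccr7, Ly6c1 rose with a log2 fold change of 3.17 (SE 0.27). Naive and stem-like genes rose in 16 of 19 cases and fell in 2, with 16 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.1e-05; adjusted p = 0.197 with an estimated correlation), among them Nsg2 at 4.11 (SE 0.27), or 4.92 without circulating replicate 2, and Dapl1 at 3.77 (SE 0.17), or 4.57 on thinning. The residency list was not called (camera, Benjamini-Hochberg adjusted p = 0.106), with 7 of 24 members higher and 13 lower, and 7 and 13 adjusted over the list alone. Itgae of this list rose, while Ccr8, the chemokine gene Xcl1 and Cdh1, which encodes the CD103 ligand E-cadherin, fell, Xcl1 with -3.31 (SE 0.38) and Cdh1 with -2.86 (SE 0.35). Levels of these last genes were low, Xcl1 at 0.161 ± 0.0374 against 1.56 ± 0.604 CPM and Cdh1 at 0.170 ± 0.0774 against 1.21 ± 0.180 CPM.

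The Th2 list fell, with 14 of 20 members lower and 1 higher, and 1 and 14 adjusted over the list alone for higher and lower (camera, Benjamini-Hochberg adjusted p = 0.00117; adjusted p = 0.197 with an estimated correlation). Calca, encoding calcitonin gene-related peptide, was at 27.4 ± 2.54 against 179 ± 15.7 CPM, and Plin2, a lipid droplet protein, fell with a log2 fold change of -1.80 (SE 0.06). Th1 and cytotoxic genes rose in 13 of 18 cases and fell in 0, with 13 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.3e-05; adjusted p = 0.197 with an estimated correlation). Klrg1, an inhibitory lectin receptor, rose with 3.36 (SE 0.06) and Nkg7, a granule protein, with 2.90 (SE 0.07). Klrg1 and Gzmb of this list are leading genes of the Treg-like cluster 5. In conventional cells, which leave that cluster out, 14 of 18 members rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 2.0e-05, and 0.191 with an estimated correlation). Th17 genes rose in 9 of 11 cases and fell in 2, with 9 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0102; adjusted p = 0.197 with an estimated correlation), at low levels such as 1.93 ± 0.717 against 0.338 ± 0.132 CPM for Il22. The Treg list had 13 of 17 members higher and 2 lower, with 13 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.9e-04; adjusted p = 0.197 with an estimated correlation), and Tigit, an inhibitory receptor, rose with 2.29 (SE 0.12). In the Tfh list 9 of 11 rose and 1 fell, with 9 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.1e-04; adjusted p = 0.197 with an estimated correlation), led by Slamf6 at 2.97 (SE 0.06).

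Proliferation genes rose in 18 of 18 cases and fell in 0, with 18 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.7e-08; adjusted p = 0.197 with an estimated correlation). Pclaf, a partner of the replication clamp, was at 55.3 ± 0.247 against 6.44 ± 1.36 CPM and Birc5, the mitotic protein survivin, at 30.1 ± 1.38 against 3.41 ± 0.138 CPM. Interferon response genes rose in 16 of 19 cases and fell in 0, with 16 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.3e-05; adjusted p = 0.197 with an estimated correlation). Ifi27l2a was at 1560 ± 141 against 288 ± 47.2 CPM, and Irf7, a factor that amplifies the interferon response, rose with 1.46 (SE 0.06). The dissociation and immediate early list fell, with 16 of 20 members lower and 1 higher, and 1 and 16 adjusted over the list alone for higher and lower (camera, Benjamini-Hochberg adjusted p = 9.6e-05; adjusted p = 0.214 with an estimated correlation). Egr1, an immediate early factor, was at 33.7 ± 0.890 against 125 ± 0.254 CPM, and the heat shock genes Hspa1b and Hspa1a fell with -1.64 (SE 0.05) and -1.10 (SE 0.05), although the split of reads between these near-identical copies is uncertain, as it is for Ly6c1 and its paralog.

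Integrin and adhesion genes rose in 15 of 22 cases and fell in 3, with 15 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00497; adjusted p = 0.197 with an estimated correlation). Itgb1, the integrin beta 1 chain, was at 455 ± 21.4 against 108 ± 5.67 CPM. Inhibitory and costimulatory receptors rose in 14 of 17 cases and fell in 1, with 14 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.0e-04; adjusted p = 0.197 with an estimated correlation). Entpd1 and Nt5e, which together turn extracellular ATP into adenosine, rose with 2.02 (SE 0.07) and 2.00 (SE 0.12). The glycolysis and hypoxia list was called narrowly (camera, Benjamini-Hochberg adjusted p = 0.0478; adjusted p = 0.214 with an estimated correlation), with 12 of 19 members higher and 5 lower, and 13 and 5 adjusted over the list alone. Its adjusted p was 0.110 without circulating replicate 1, 0.0784 without TRM replicate 2 and 0.0655 without circulating replicate 2 (camera, Benjamini-Hochberg). With the replicate block the list was not called either (camera, Benjamini-Hochberg adjusted p = 0.0722). Egln3, an oxygen sensor, rose with 1.30 (SE 0.06), while Hk2, a hexokinase, and Vegfa fell with -1.46 (SE 0.10) and -2.11 (SE 0.16).

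The remaining lists were not called. TCR and NF-kB response genes rose in 7 of 23 cases and fell in 13, with 7 and 13 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.106), among them Nfkbid at -1.85 (SE 0.07) and Egr2 at -1.54 (SE 0.12). Lipid handling genes rose in 8 of 19 cases and fell in 6, with 9 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.378), Hmgcs1 of sterol synthesis with 0.82 (SE 0.06). Chemokine receptors rose in 7 of 15 cases and fell in 5, with 7 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.356), Ccr3 with 4.20 (SE 0.16), Ccr10 with 3.51 (SE 0.18) and Ccr9 with -3.01 (SE 0.30), although thinning took Ccr3 to 3.41 and Ccr10 to 2.71. Chromatin regulators rose in 6 of 25 cases and fell in 11, with 6 and 12 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.378), Runx3 with 1.23 (SE 0.05) and the DNA methyltransferase gene Dnmt3a with -0.82 (SE 0.06). Cytokine receptors rose in 12 of 25 cases and fell in 8, with 12 and 8 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.356), Il6st with 2.24 (SE 0.09) and Il17rb with -1.42 (SE 0.12).

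**Figure D3:**
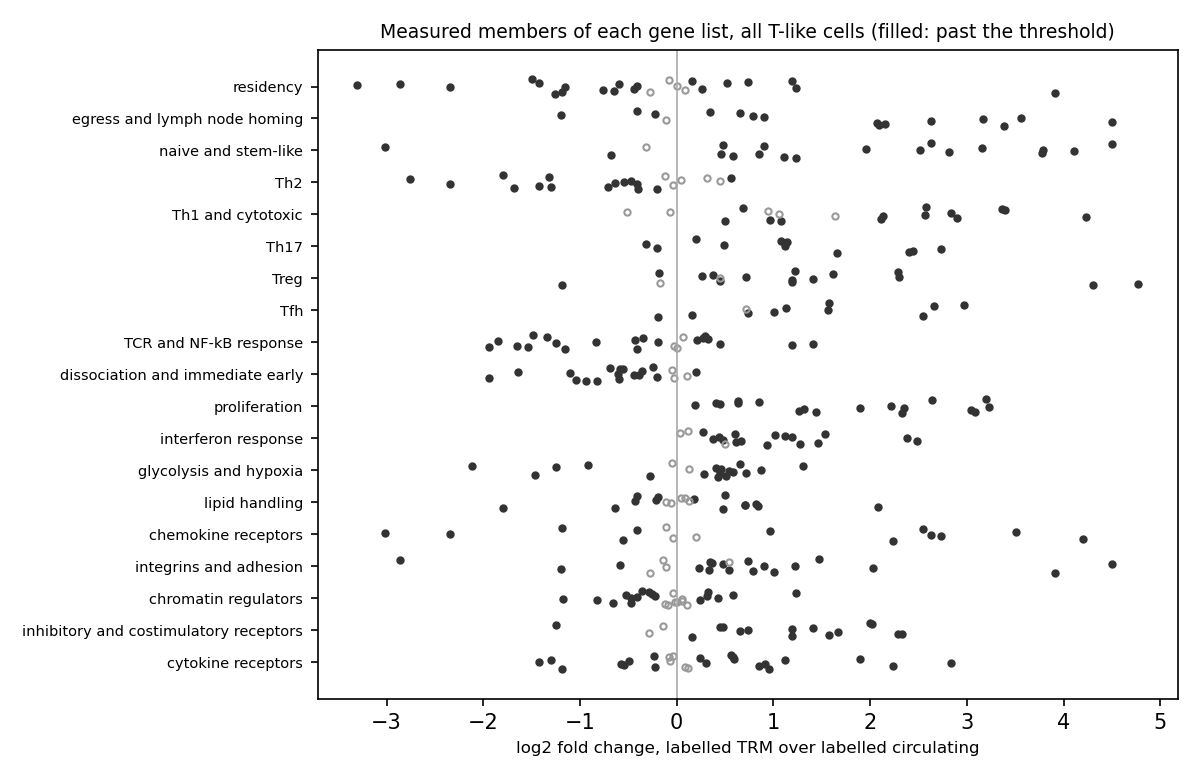
Log2 fold changes (labelled TRM over labelled circulating) of the measured members of the 19 gene lists in all T-like cells, with filled points for genes past the threshold and open points for the others. All 18 proliferation genes lie above 0, and 14 of the 20 Th2 genes fell.

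Markers of other cell types moved with the groups. Calca and Il1rl1 of the Th2 list also stand among the markers of type 2 innate lymphoid cells fixed here, of which Arg1, Rnf128, Cxcl2 and Hs3st1 fell too, with -3.95 (SE 0.25), -2.60 (SE 0.06), -2.21 (SE 0.24) and -1.25 (SE 0.09), while Klrg1 rose. Klrg1 is a leading gene of the Treg-like cluster 5. Cd4, the gene of the sorted marker, was at 195 ± 5.16 against 89.6 ± 2.53 CPM, and of the T cell receptor complex Trbc2 and Cd3d rose with 0.87 (SE 0.06) and 0.64 (SE 0.06), while Trac and Cd3e, at -0.13 (SE 0.06) and 0.03 (SE 0.06), did not pass. Lyz2, a macrophage gene, was at 1.37 ± 0.258 against 2.71 ± 0.0586 CPM in T-like cells, and Sftpc, a gene of the alveolar epithelium, at 0.284 ± 0.0219 against 1.68 ± 0.640 CPM, both higher in the libraries labelled circulating. Cd74 and H2-Aa of the MHC class II pathway, fixed here as dendritic cell markers, went the other way, at 126 ± 4.19 against 5.39 ± 0.227 CPM and 19.9 ± 0.117 against 2.15 ± 0.340 CPM. Non-T cells made up 0.296% ± 0.0315 of the cells (SD, n = 2) in the libraries labelled TRM and 0.485% ± 0.0582 in those labelled circulating (exact permutation test, two-sided, p = 0.33, the smallest this design allows). Among them, a UMI of C1qa, C1qb or Mrc1, genes of tissue macrophages, was seen in 13 of 32 and 12 of 24 cells labelled TRM and in 40 of 47 and 25 of 34 labelled circulating, and a B cell marker in 16 and 8 against 2 and 2.

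The comparison was repeated in conventional cells, which leave out the Treg-like and naive-like clusters, to ask whether the differences rest on those clusters. Cluster 6, which has 3 naive markers, stays in the conventional class. It holds 2890 and 2468 cells labelled TRM and 211 and 185 labelled circulating, so cells with naive features are not fully removed. S1pr1 was at 184 ± 0.595 against 16.3 ± 0.710 CPM (labelled TRM against labelled circulating, mean ± SD, n = 2), 10.8-fold higher, and Klf2 at 979 ± 33.5 against 201 ± 18.5 CPM. Cd69 was at 373 ± 5.66 against 829 ± 49.5 CPM and Il1rl1 at 107 ± 2.87 against 302 ± 4.41 CPM. Itgae had a log2 fold change of 2.46 (SE 0.11) here against 3.91 in all T-like cells, and Foxp3 2.00 (SE 0.24) against 4.30, and the difference between the populations was not tested. Foxp3 moved to 0.87 with clusters made without called genes and to 1.19 on thinning. It lost its call, at 0.50, when the cells were clustered anew with called doublets kept. That clustering left 8270 and 7123 cells labelled TRM in the class instead of 8950 and 7723, and in it a further cluster, of 593 cells led by proliferation genes, met the Treg-like rule, so the loss is not credited to the 5 doublets.

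Of 12913 genes tested with edgeR, 4003 were higher and 4105 lower in the libraries labelled TRM, 920 and 1150 of them at least 2-fold. DESeq2 called 3305 and 2406, and the test against a 2-fold change 563 and 458. RLE scaling gave 4154 and 3953, and library totals only 4438 and 3644. Of the 12907 genes tested in both populations, 7751 were called in both with the same sign and 5 with opposite signs. Conventional cells came mostly from clusters 6, 1 and 0 in the libraries labelled TRM and from clusters 13, 14 and 4 in those labelled circulating. Of all 15 clusters, 13 drew over 90% of their cells from 1 group, so the comparison sets largely separate clusters against each other.

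The highest genes were Cd7, Ms4a4b, Pglyrp1, Tnfrsf19, Esm1, S1pr1, Hist1h1b, Cd9, Cdc25b and Rhoc. Cd7 was at 39.0 ± 0.708 against 2.30 ± 0.417 CPM and Cd9, a tetraspanin, at 97.0 ± 5.54 against 9.21 ± 0.0617 CPM. Hist1h1b, a linker histone, rose with a log2 fold change of 3.36 (SE 0.07), or 2.37 on thinning, 1.14 with clusters made without called genes and 1.38 in the clustering with called doublets kept. Without the cluster holding 3 naive markers, an alternative chosen after the data had been seen, Cd7 was at 4.82 and Cd9 at 2.59. The lowest were Hlf, Pde3b, Fgl2, Gpr65, Ctla2a, St6galnac3, Ccr8, Ier5l, Ctla2b and Spata7. Hlf was at 5.36 ± 0.479 against 64.0 ± 2.03 CPM, and the paralogs Ctla2a and Ctla2b, between which the split of reads is uncertain, fell with -2.41 (SE 0.06) and -2.01 (SE 0.05). Ccr8, at -2.21 (SE 0.23), lost its call in edgeR without TRM replicate 1 (Benjamini-Hochberg adjusted p = 0.0648) and without TRM replicate 2 (adjusted p = 0.0507).

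Among panel genes in conventional cells, Ifng rose with 1.30 (SE 0.09) and Il5 fell with -1.48 (SE 0.09), while Gata3 at -0.12 (SE 0.06), Itga1 at -0.08 (SE 0.18) and Prdm1 at -0.16 (SE 0.11) did not pass, Prdm1 passing only without TRM replicate 2 at -0.29. No direction is read for Itga1, which lay between -0.29 without circulating replicate 2 and 0.37 without the cluster holding 3 naive markers, and turned without circulating replicate 1 (0.17) and without TRM replicate 2 (0.05). Il17a, at 1.22 (SE 0.39), lost its call without circulating replicate 1 (0.61) and with DESeq2, and was at 2.28 without circulating replicate 2. Il4, at -0.22 (SE 0.08), passed narrowly in edgeR (Benjamini-Hochberg adjusted p = 0.0467) and did not pass without TRM replicate 1 (-0.10), without circulating replicate 2 (-0.16) or with DESeq2, and it turned to 0.0703 on thinning. Areg no longer passed with cells thinned to 2000 UMIs, at -0.10. With the cluster holding 3 naive markers left out as well, Il4 turned to 0.0634 and Prdm1 to 0.21, Gata3 turned to 0.20 and passed (edgeR, Benjamini-Hochberg adjusted p = 0.00713), and Il13 and Bhlhe40 lost their calls at -0.12 and -0.08.

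Of the gene lists, camera called 12 in conventional cells at the preset correlation, 10 higher and 2 lower. With an estimated correlation, again on 2 residual degrees of freedom, it called 0 of the 19, of which 4 had an unadjusted p under 0.05, and fry called 18. Proliferation genes rose in 18 of 18 cases and fell in 0, with 18 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.3e-08; adjusted p = 0.191 with an estimated correlation). The Th2 list had 13 of 20 members lower and 1 higher, with 1 and 13 adjusted over the list alone for higher and lower (camera, Benjamini-Hochberg adjusted p = 0.00296; adjusted p = 0.255 with an estimated correlation), and the Treg list 11 of 17 higher and 3 lower, with 11 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00570; adjusted p = 0.247 with an estimated correlation). The glycolysis and hypoxia list was not called here (camera, Benjamini-Hochberg adjusted p = 0.0644). In the chemokine receptor list, also not called, the median log2 fold change was -0.07 and the mean 0.34.

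Shares of T-like cells with a UMI went the same way as the CPM for most genes. After thinning, which left out 2.24% and 1.23% of the cells labelled TRM and 7.13% and 4.13% of those labelled circulating, S1pr1 was detected in 26.9% ± 0.0727 and 2.38% ± 0.133 of cells (labelled TRM and labelled circulating, SD, n = 2) and Klf2 in 69.0% ± 0.647 and 21.2% ± 0.401. Cd69 was detected in 44.0% ± 0.635 and 63.7% ± 2.01 and Il1rl1 in 16.3% ± 0.212 and 36.1% ± 0.373. Foxp3 was detected in 3.44% ± 0.422 and 0.217% ± 0.0360, Ccr7 in 17.8% ± 0.532 and 2.41% ± 0.197, Itgae in 5.50% ± 0.183 and 0.368% ± 0.114, and the proliferation gene Mki67 in 2.97% ± 0.0114 and 0.622% ± 0.0286. The remaining shares were 21.1% and 41.5% for Cxcr6, 27.4% and 36.9% for Cd44, 56.7% and 63.0% for Gata3, 1.04% and 3.41% for Il5, 3.68% and 5.40% for Il13, 1.84% and 0.719% for Ifng and 0.0864% and 0.0395% for Il17a. Each of these differences was larger than the spread between replicates, with an exact permutation p of 0.33, the smallest possible. The Areg share, 31.5% and 22.0%, and the Il4 share, 9.10% and 8.73%, went against their CPM, and the Il4 difference turned without circulating replicate 1 (-0.00487 percentage points) and without TRM replicate 2 (-0.254 percentage points), so no order is read from them. Nor is one read for Itga1, at 0.388% and 0.471% after thinning and 0.902% and 0.847% unthinned.

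Unthinned, S1pr1 was seen in 46.2% and 4.33% of cells, Klf2 in 85.9% and 30.9%, Cd69 in 67.4% and 77.8%, Cxcr6 in 31.5% and 56.0%, Il1rl1 in 28.6% and 52.1%, Foxp3 in 7.17% and 0.300%, Itgae in 10.8% and 0.790% and Mki67 in 7.38% and 1.18%. The only other cells, the 137 non-T cells with a median of 5710 UMIs, are a poor background, since Cd3e was detected in 54.7% of them. S1pr1 was seen in 26.3% of them, Klf2 in 62.0%, Cd69 in 55.5%, Cxcr6 in 30.7%, Il1rl1 in 26.3%, Foxp3 in 2.19%, Itgae in 3.65% and Mki67 in 1.46%. The unthinned shares of S1pr1, Klf2, Ccr7, Foxp3, Itgae, Ifng, Mki67 and Areg labelled circulating lie below the non-T shares. The non-T cells may express these genes themselves or carry T cell RNA, so this comparison cannot tell whether those shares are background. For Cd44 and Il5 the unthinned shares, 53.3% and 58.0% for Cd44 and 1.76% and 5.67% for Il5, lie below the non-T shares of 65.7% and 5.84% in both groups. The Il5 value rests on 8 of the 137 non-T cells. For the same reason this comparison gives no background level for either gene, and no difference in expressing cells is read from it.

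**Figure D4:**
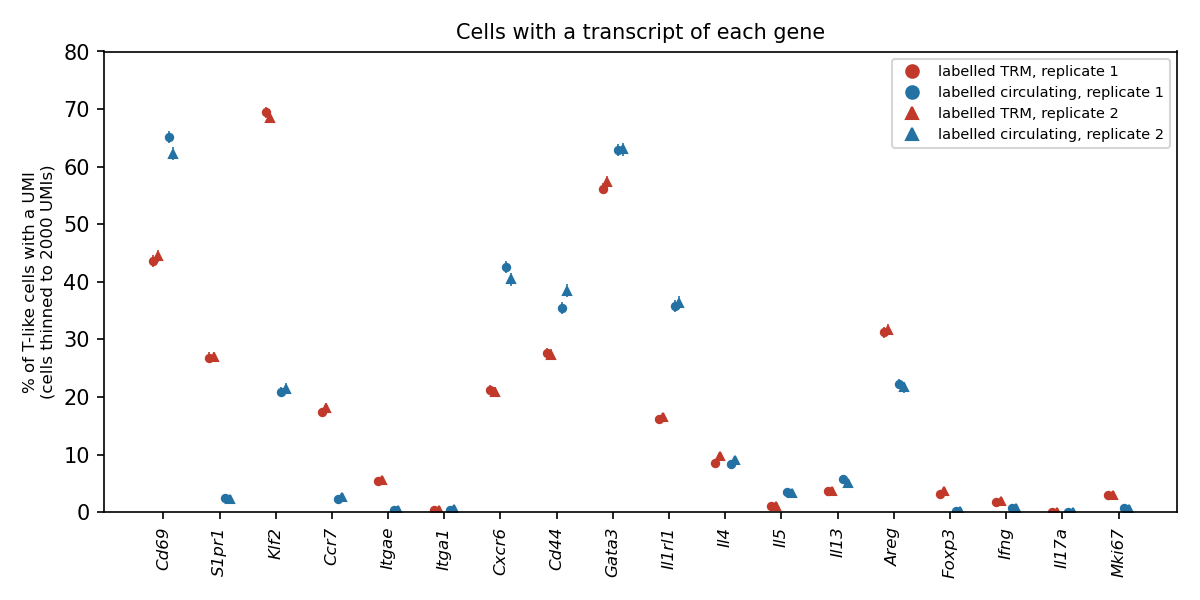
Percentage of T-like cells with at least 1 UMI of each gene after thinning to 2000 UMIs, with points for libraries and bars for exact binomial 95% intervals. S1pr1 was detected in 26.9% of cells labelled TRM and 2.38% labelled circulating, and Cd69 in 44.0% and 63.7%.

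T cell receptor beta transcripts were dominated by the same variable segments in every library. Trbv13-2, the segment of the DO11.10 receptor, gave 61.4% and 61.2% of Trbv UMIs in the libraries labelled TRM and 55.7% and 55.8% in those labelled circulating. Trbv12-1 and Trbv12-2, the segment family of the OT-II receptor, together gave 34.4% and 35.0% against 38.1% and 38.4%, and all other segments between 3.83% and 6.24%. The groups did not overlap in any of these shares, with an exact permutation p of 0.33 for each. The alpha segment family of the OT-II receptor, Trav14, gave only 152 and 189 UMIs in the libraries labelled TRM and 168 and 199 in those labelled circulating. Which donor line was used is therefore not read from these segments.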

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

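The fold threshold of 2, the removal of the highest doublet scores, the removal of the cluster with 3 naive markers and the left-out libraries for lists and shares were chosen after the data had been seen. Of 2382 values of 138 named-gene results, 2300 kept their direction and side of the threshold, 69 were no longer past it, 3 newly passed and 10 reversed; 3 of 119 share values reversed. DESeq2 called 2580 genes lower in all T-like cells and 2406 in conventional cells, and the test against a 2-fold change called 615 higher and 497 lower, and 563 and 458, because it asks for a larger change. With an estimated correlation 0 gene lists were called in either population, in a test that rests on 2 residual degrees of freedom. In conventional cells Itga1 reversed to 0.0188 with called doublets kept and the cells clustered anew, which left 8270 and 7123 cells labelled TRM in the class instead of 8950 and 7723, 0.0107 at 5% mitochondrial UMIs, 0.0410 at resolution 2 and 0.37 without the cluster with 3 naive markers, and ranged from -0.29 to 0.17 with a library left out. Without that cluster Prdm1, Gata3 and Il4 reversed too, to 0.21, 0.20 and 0.0634, and Il4 reversed to 0.0703 on thinning. The unthinned Itga1 share differed by 0.0552 percentage points, and the Il4 share difference ranged from -0.254 to 0.980 with a library left out; the cause was not tested. A left-out library leaves 1 in its group, which is taken to vary as the other group does. The replicate numbers are not stated to pair the samples: same-numbered libraries deviated together over genes of at least 20 CPM (r = 0.647 across 4660 genes, which are not independent replicates) and hardly over all genes (0.105), in conventional cells 0.630 and 0.104, and with the replicate block 4520 genes were higher and 4720 lower in all T-like cells, 4383 and 4579 in conventional cells, and 12 lists were called in each, without the glycolysis and hypoxia list in all T-like cells (camera, Benjamini-Hochberg adjusted p = 0.0722); Gzmb and Spata7 did not pass and Gata3 in conventional cells did. Tests within Treg-like and naive-like cells and of the difference between classes, with their alternatives, were not run, since libraries labelled circulating held under 50 such cells. Depth limits Zfp683, which was too rare to test.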

Other observations

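The lists in the next paragraph were written, and the tests of exchanged labels, of the compartment, of the replicates and of B cell and myeloid RNA were chosen, only after the results had been seen.

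MHC class II genes were higher in the libraries labelled TRM. In all T-like cells 6 of 8 measured members rose and 0 fell (camera, Benjamini-Hochberg over 3 such lists, adjusted p = 2.9e-04; adjusted p = 0.264 with an estimated correlation), H2-Eb1 with a log2 fold change of 3.41 (SE 0.09) and H2-Ab1 with 1.87 (SE 0.08). Sterol synthesis genes rose in 12 of 20 cases and fell in 2 (camera, Benjamini-Hochberg adjusted p = 0.00754; adjusted p = 0.265 with an estimated correlation), Cyp51 with 0.91 (SE 0.06) and Msmo1 with 0.89 (SE 0.07). Targets of the integrated stress response fell in 12 of 19 cases and rose in 4 (camera, Benjamini-Hochberg adjusted p = 0.0177; adjusted p = 0.265 with an estimated correlation). Trib3 fell with -3.12 (SE 0.15), Atf5 with -2.71 (SE 0.09) and the asparagine synthetase gene Asns with -1.62 (SE 0.10), while the transcript of Atf4, the factor that drives these genes, was at -0.01 (SE 0.05) and did not pass. These lists were written after the leading genes of the clusters had been seen, Atf5, Aars and Cebpg leading a cluster found almost only in the libraries labelled circulating, so they are not independent evidence of their direction.

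S1pr1 and Klf2 were higher, and Cd69 and Cxcr6 lower, in the libraries labelled TRM. A response to digestion is not excluded. In the 5.98% to 6.53% of cells with no UMI of Fos, Fosb, Jun or Egr1 the S1pr1 log2 difference was 2.36, against 3.44 in all cells. Klf2 was at 1.32 against 2.22, Cd69 at -1.05 against -1.21 and Cxcr6 at -1.05 against -1.13. Ccr7, at 3.43 against 2.69, and Rgs1, at -0.85 against -0.59, were larger in those cells. A missing UMI can come from low depth, and the depth of those cells was not examined. They need not have escaped the response, so these values cannot decide the question. A difference in depth per cell is argued against for these 4 genes. With cells thinned to 2000 UMIs, S1pr1 kept a log2 fold change of 3.47 (SE 0.07). The shares of thinned cells, labelled TRM and labelled circulating, were 69.0% and 21.2% for Klf2. They were 44.0% and 63.7% for Cd69 and 21.1% and 41.5% for Cxcr6. An exchange of the labels or files stays open. Non-T cells labelled circulating carried C1qa, C1qb or Mrc1 in 80.2% of cases against 44.6% labelled TRM (Fisher's exact test over cells, not libraries, odds ratio 5.04, p = 2.2e-05), as tissue cells would. A B cell marker was in 16 and 8 non-T cells labelled TRM and in 2 and 2 labelled circulating, and Sftpc was higher in the libraries labelled circulating. But macrophages are autofluorescent and could also have entered an antibody-positive gate. Itgae, of the residency list, runs as the labels say, with a log2 fold change of 3.91 in all T-like and 2.46 in conventional cells. Itgae is among the 7 of 24 members of that list that rose, against 13 that fell, and it is a leading gene of the Treg-like cluster 5. Runx3, another of the 7, rose with a log2 fold change of 1.23 (SE 0.05) in all T-like cells. That antibody-negative cells truly carry more egress transcripts cannot be told apart from an exchange, since the files hold 0 features other than transcripts that would place a cell in tissue or blood. Neither reading was used to regroup a library.

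Replicates 1 and 2 of each group had cluster proportions that differed by no more than the sampling of cells (chi-square test, p = 0.694 for the libraries labelled TRM and 0.373 for those labelled circulating). That is consistent with both replicates being portions of 1 pool of cells, in which case the adjusted p-values measure technical spread alone. A single library entered under 2 numbers is argued against, since at most 0.274% of barcodes were shared between replicates. The UMI counts also differed by more than independent draws of UMIs would give, with a mean chi-square per gene of 16.2 and 30.4 and medians of 1.06 and 1.32. The UMIs of a cell are not independent draws, so these values do not show a difference beyond the sampling of cells. Separate animals with like composition stay open and were not tested.

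Cd74 and H2-Aa were higher in the libraries labelled TRM although the sort was for CD4 T cells. RNA or doublets of B cells and myeloid cells are argued against, because the ratios of Cd79a and Lyz2 to Cd74 in T-like cells, at the median of both, were at most 0.0234 times those in the non-T cells of the same library in the libraries labelled TRM. The Treg-like cluster as the only source is argued against too, since Cd74 had a log2 fold change of 3.28 (SE 0.09) without the Treg-like and naive-like clusters, against 4.49 with them. The cells left still held 98 and 143 Foxp3 UMIs labelled TRM and 24 and 24 labelled circulating. Treg cells outside that cluster are therefore not excluded as a source. Expression by the T cells themselves may remain as a hypothesis; RNA of a dendritic cell type without Cd79a and Lyz2 was not tested.

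In every library Trbv13-2 and Trbv12 transcripts were found in the same cells more often than independent detection gives, with odds ratios of 1.47, 1.55, 2.25 and 2.64; depth per cell also raises such a ratio, and no explanation was tested.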
